A study of Rattus norvegicus with 6 samples.

How the data were processed

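Gene expression was measured by 1-colour Affymetrix array in 6 samples of rat cortical progenitor cells, 3 given vehicle and 3 given 1 µM corticosterone. Per the labels' protocols, total RNA was extracted with TRIzol, its quality was looked at on a Bioanalyzer, cDNA was made from 3 µg with an oligo(dT) primer that carries a T7 promoter, and biotin-labelled cRNA was made from it by in vitro transcription. Priming from the poly(A) tail weights the signal towards the 3′ end, so probe sets in different parts of a transcript can differ.

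The deposited values are signal intensity per probe set on a linear scale, 1 value per array, and the authors made them with MAS5, per the submitters' processing notes. MAS5 subtracts a local background, sets mismatch against perfect-match probes and summarises the probes of a set. Its version, its detection calls and any other setting are not given in the sources used here. The values show that each array was scaled to one mean, since the mean without the lowest and highest 2% of probe sets was 500.2 on each of the 6 arrays. Such scaling fixes the mean of the linear signals, so the medians of the arrays can still differ. Low MAS5 signals are noisy on a log scale, which is why a pseudocount was added and the dimmest probe sets were left out.

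The table held 31099 probe sets, of which 57 are control probe sets and were left out of every test. The platform annotation gave 1 gene symbol for 20832 of the rest, several for 436 and none for 9780. No gene was named from a probe set with several symbols or none. Entrez identifiers of 20764 probe sets were found in the NCBI gene table of assembly GRCr8, used for names only, and 0 symbols needed an update. No genome positions are given, since no build was used. Rig1 is that annotation's symbol for the RNA sensor listed as Ddx58.

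Signals were transformed to log2(signal + 28.6), where the pseudocount is the 25th percentile of all values. A fold change is therefore on the log2(signal + pseudocount) scale and understates the change of low genes. The 40% of probe sets with the lowest mean log2 signal over all 6 arrays were left out, which corresponds to a signal of 63.6 and left 18625. The background signal of 22.8 is the 95th percentile of 27 bacterial control probe sets with no spiked target. Where a gene lay at or under it on all 3 vehicle arrays, the ratio of the geometric mean of the corticosterone signals to that background is given as at least N-fold. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with treatment and couple as terms. Adjusted p-values are Benjamini-Hochberg values over the 18625 probe sets, with a threshold of 0.05, and all tests are two-sided.

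Replicate numbers in the titles run from 1 to 3 in both groups, and the series design text says that the RNA samples form couples of a treated and a vehicle sample, so the couple was a term of the model. In a check of the pairing, deviations from the group means correlated by 0.57, 0.52 and 0.35 between samples with the same number, and by −0.48 to 0.003 between samples with different numbers. Deviations of the 3 samples of a group cancel out, so positive values for the same number push the others down, and the contrast is partly arithmetic. Correlations here are across probe sets, which are not independent replicates. Nothing states that the couples came from separate cultures or animals. The p-values therefore measure only the spread of the differences within these 3 couples, which may be technical. That spread is drawn towards the one of probe sets with a similar signal, so small p-values also rest on other probe sets. Without the intensity trend 1262 probe sets passed. No batch, scan date or other grouping of the arrays is given in the sources used here.

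One probe set stood for each gene, the one with the highest mean log2 signal over all arrays, which gave 9910 genes. Several tested probe sets measured 2911 of these genes, among them 588 of the genes that changed. For 275 of the changed genes another probe set also passed in the same direction, and for 1, Asrgl1, another passed in the opposite direction.

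A total of 23 gene lists were tested, and 10 reference genes and 3 sex-linked genes served as checks. Lists were tested with limma's camera at its preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry. Adjusted p-values are Benjamini-Hochberg values over the 23 lists. With the preset correlation 10 lists passed, 7 higher and 3 lower. With an estimated correlation 0 lists did, 1 was at an unadjusted p under 0.05, and the adjusted p lay from 0.37 to 0.94. Camera with an estimated correlation rests on few residual degrees of freedom here, so it does not decide whether correlation explains a call. The cholesterol, glucose and interferon lists had estimated correlations of −0.034, −0.034 and −0.088, under the preset one. Their adjusted p was 0.37 all the same. The other lists that passed at the preset correlation had estimates above it. With fry, which asks whether the members of a list move 1 way on balance and does not compare them with other genes, 14 lists passed. These held 9 of the 10 that passed with camera, the DNA replication list being the exception, and 19 lists passed with fry's test for change in either direction. Lists past with fry and not with camera were those of G1 cyclins, microglia and macrophages, NF-kB, the circadian clock and growth factors (fry adjusted p from 0.018 to 0.034). Some genes stand in more than 1 list. The number of members past the threshold is given over all probe sets and with p-values adjusted over the list alone.

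The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 15 genes with the largest rise and the 15 with the largest fall among those past the threshold with 1 direction in all 3 couples, the 4 members of each list with the smallest p, and Nr3c1, Nr3c2, Fkbp5, Tsc22d3, Sgk1 and Per1, which came to 126 tested genes. Rhob, Dll1, Scg3, Bcl11b, Elavl2, Ina, Nefm, Tubb3, Cnp, Galc, Vcan, Bcan, Mmp15, Insig2, Phgdh, Pfkp, Mx2, Tgfa, Dusp5, Etv1, Csnk1e and Asrgl1 were named after their values were seen, as were the genes that only the closing part names.

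Alternatives were no pseudocount, a pseudocount at the median, no filter and a stricter filter on low signals, quantile normalization, centring each array on its median, no couple in the model, no intensity trend, a threshold of 0.10, the mean of a gene's probe sets in place of the brightest, and each couple left out in turn. The model was tested on simulated data of 18625 probe sets for corticosterone against vehicle, with 200 changed probe sets in each of 20 runs. It recovered 75.5% of changes of 1.5-fold, 97.3% of 2-fold and 99.9% of 3-fold, and 7.43% of its calls were false. Without the couple it recovered 10.5%, 56.4% and 90.4%. The simulated arrays carried the couple effects of the same fit, with independent noise for each probe set. Their residual spread was that of the fit after it was drawn towards probe sets with a similar signal, which may favour the model tested. A model without the couple had to do worse on these arrays, so the simulation does not show that the couple belongs in the model. The false share holds for 200 changed probe sets, fewer than were called in the data.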

Results

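Gene expression was measured in neuronal progenitor cells, the dividing precursors of neurons and glia, taken from the rat cerebral cortex at embryonic day E15.5 and grown on fibronectin. The medium held 20 ng/ml basic fibroblast growth factor (bFGF), a mitogen that keeps such cells dividing. Cultures received 1 µM corticosterone, the main glucocorticoid of rodents, or its solvent dimethyl sulfoxide (vehicle) for 48 h. The comparison asks which transcripts the hormone changed. RNA of 6 samples, 3 per treatment, was hybridised to 1 Affymetrix array each, and the samples formed 3 couples of 1 vehicle and 1 corticosterone sample. The number of arrays limits the precision of every value. The median signal of the 31099 probe sets was 108, 122 and 119 on the vehicle arrays of couples 1, 2 and 3, and 124, 134 and 125 on their corticosterone arrays. The share of probe sets above the background signal of 22.8 was 75.3%, 78.1% and 77.9% on the vehicle arrays and 80.02%, 80.7% and 78.3% on the corticosterone arrays. The ratio of 3′ to 5′ signal of Actb, a sign of RNA integrity, was 1.55, 2.11 and 2.12 with vehicle and 1.76, 2.0 and 2.03 with corticosterone. Across genes, which are not independent replicates, the correlation of log2 signals between arrays lay between 0.946 and 0.984.

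Corticosterone changed 2953 of the 18625 probe sets tested (15.9%) at a limma adjusted p under 0.05, of which 1751 rose and 1202 fell. They covered 1928 of 9910 genes, with 1158 higher and 770 lower. Among these genes 242 rose and 24 fell at least 2-fold, and 31 rose at least 4-fold. The change had 1 direction in all 3 couples for 1923 of the 1928 genes. The threshold favours genes whose couples agree, so this is no separate support for the calls. Without the couple as a block 417 probe sets passed, and 1677 passed without couple 1 and 1192 without couple 2. After centring each array on its median, 30.4% of the changed probe sets were higher, against 59.3% with the authors' scaling and 56.4% with quantile normalization. The centring moved the median log2 fold change of the probe sets tested to −0.11 from −0.004. It used the median of all probe sets but the controls, dim ones included. Without the filter on low signals the median log2 fold change was 0.028 with the authors' scaling.

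The largest rise among the genes tested was that of Aldh1a3, a retinaldehyde dehydrogenase that makes retinoic acid. Its signal was 14.0 ± 7.42 (SD, n = 3 arrays per group, as for every signal given here) with vehicle and 642 ± 268 with corticosterone, a log2 fold change of 3.90 ± 0.20 (SE; limma adjusted p = 4.2e-06). Its vehicle signal lay at background on all 3 arrays, so the rise was at least 26.2-fold. By the same bound Plau, the urokinase plasminogen activator, rose at least 12.1-fold, the tropomyosin Tpm2 at least 11.6-fold and the small heat shock protein Hspb1 at least 10.8-fold. The caveolar coat gene Cav1 rose from 79.1 ± 38.3 to 1054 ± 609 (log2 fold change 3.23, adjusted p = 1.5e-05), and the galectin Lgals1 from 1497 ± 435 to 8631 ± 3329 (2.48, adjusted p = 9.2e-07). S100a11 and S100a4, of the S100 calcium-binding proteins, rose by 3.71 and 2.71, the annexins Anxa2 and Anxa5 by 2.63 and 2.43, and Lgals3 by 2.77. Myof, Akap12, the chemokine Ccl2 and the secreted guidance protein Sema3e rose by 2.80, 2.66, 2.48 and 2.56. The list of meningeal, pericyte and fibroblast markers, which shares S100a4 and Anxa2 with these genes, had a median log2 fold change of 1.03 over the 13 members tested and 0.60 over all 23 named ones, those below the filter on low signals included.

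The largest fall among the genes tested was that of Pdgfra, a growth factor receptor of oligodendrocyte precursors and of mesenchymal cells. Its signal was 2134 ± 1382 with vehicle and 616 ± 393 with corticosterone (log2 fold change −1.64 ± 0.14, SE; limma adjusted p = 2.9e-05), lower in each of the 3 couples. Slc35d3, of the nucleotide sugar transporter family, fell from 8372 ± 715 to 2969 ± 727 (−1.51, adjusted p = 9.4e-06). The matrix glycoprotein Mfap4, the pluripotency-associated transcription factor Klf4 and the amino acid transporter Slc6a15 fell, with log2 fold changes of −1.55, −1.34 and −1.23. So did Ppp1r16b (−1.28), Pmel (−1.46), Scrg1 (−1.25) and Rev3l, the catalytic subunit of a translesion DNA polymerase (−1.14). C1ql1 (−1.57), Fam89a (−1.54), the neural zinc finger gene Myt1 (−1.45), B3gat2 (−1.44), Gal3st1 (−1.32) and the R-spondin receptor Lgr5 (−1.27) complete the 15. In the model without the couple Pdgfra, C1ql1, Fam89a, Myt1, B3gat2, Gal3st1 and Lgr5 did not pass (adjusted p from 0.054 to 0.29).

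**Figure D1:**
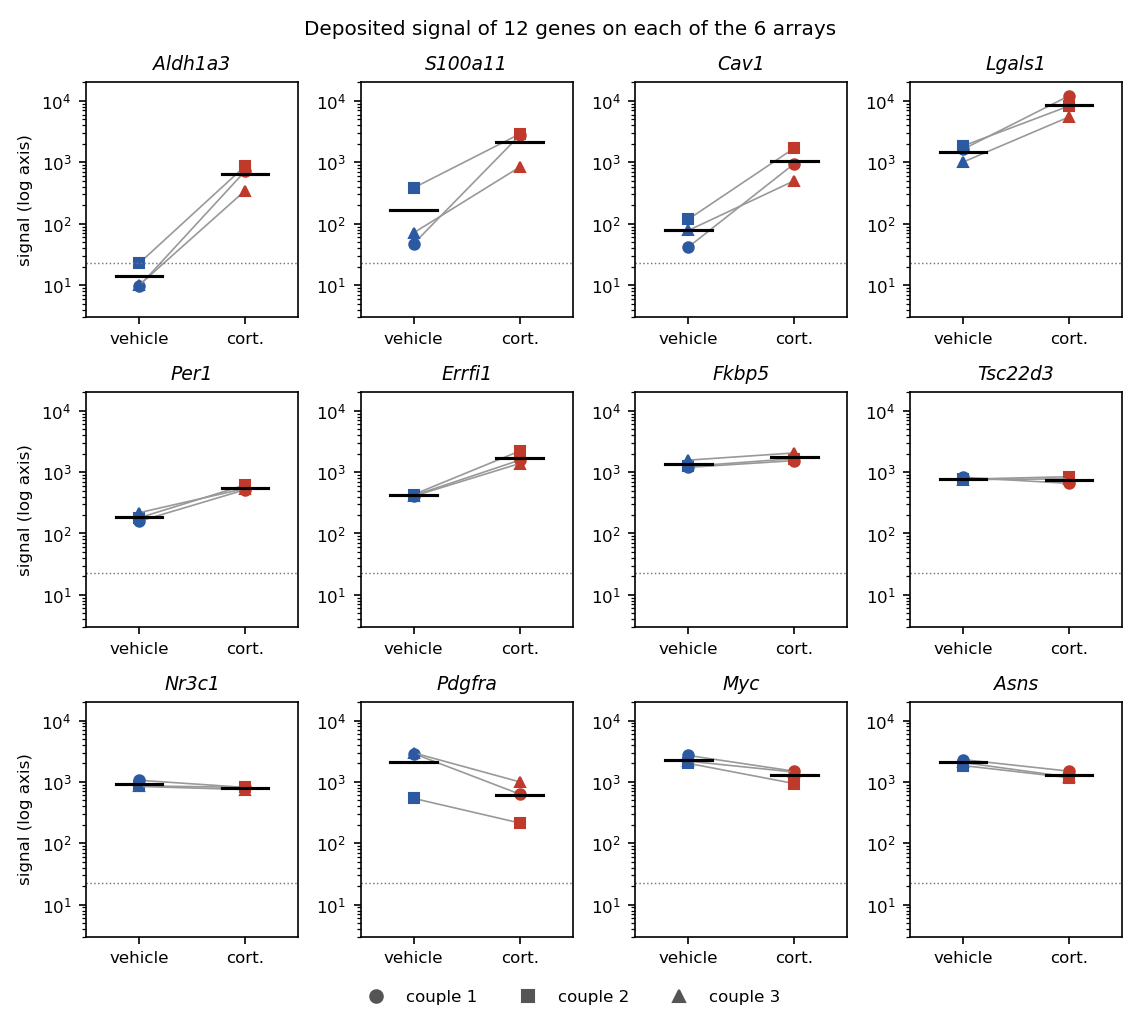
Deposited signal (log axis) of 12 genes on the 6 arrays, with the samples of a couple joined by a line, the mean of 3 arrays per treatment as a black bar and the background of 22.8 as a dotted line. Aldh1a3 was at background in all 3 vehicle samples and had a mean of 642 with corticosterone (cort.), while Tsc22d3 had means of 782 and 758.

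Of the 25 glucocorticoid receptor target genes tested, 16 rose, 1 fell and 8 did not pass, while 17 rose and 2 fell when adjusted over the list alone. The list passed as higher (camera adjusted p = 1.5e-06, adjusted p = 0.37 with an estimated correlation). Errfi1, a feedback inhibitor of the epidermal growth factor receptor, rose from 418 ± 12.8 to 1717 ± 431 (log2 fold change 1.94 ± 0.11, SE; adjusted p = 6.0e-06). Ddit4, an inhibitor of mTOR signalling, rose by 1.64, and the clock gene Per1 rose from 185 ± 30.4 to 557 ± 51.8, by 1.46 (adjusted p = 2.9e-05). The transcription factor Klf9, the kinase Sgk1 and the receptor co-chaperone Fkbp5 rose by 0.86, 0.82 and 0.38. The 1 member that fell was the small GTPase gene Rhob (−0.53). Tsc22d3, which encodes the leucine zipper protein GILZ, had signals of 782 ± 35.9 and 758 ± 94.1 (−0.05, adjusted p = 0.79). Without the couple as a block 4 targets passed, and Klf9, Fkbp5, Sgk1 and Rhob did not (adjusted p = 0.60, 0.23, 0.062 and 0.051). Without couple 2, 11 targets passed and Sgk1 did not (adjusted p = 0.069), and Tsc22d3 turned to 0.08 without couple 1. The fit without the intensity trend left 10 targets past, and not Fkbp5 and Sgk1 (0.057 and 0.051).

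Transcript of the glucocorticoid receptor itself, Nr3c1, had signals of 923 ± 123 with vehicle and 792 ± 35.8 with corticosterone (log2 fold change −0.21, limma adjusted p = 0.15, and 0.044 with each array centred on its median). The mineralocorticoid receptor gene Nr3c2 lay below the filter on low signals, at 25.9 ± 6.32 and 43.3 ± 9.71, and was not tested. In the list of 11 genes for corticosteroid receptors, chaperones and steroid metabolism, 1 rose, 2 fell and 8 did not pass, with the same counts adjusted over the list alone. Hsd11b1, the enzyme that regenerates corticosterone from its inactive keto form, rose from 53.9 ± 9.73 to 204 ± 56.8 (1.47 ± 0.18, SE; adjusted p = 3.4e-04). The Hsp90 co-chaperones Fkbp4 and Stip1 fell by 0.27 and 0.23 on the log2 scale. The list did not pass (camera adjusted p = 0.37), with a median of −0.09, a mean of 0.06 and a test pointing down. Fkbp4 and Stip1 did not pass without the couple as a block (adjusted p = 0.21 and 0.22). Fkbp4 also did not pass without any 1 of the couples (0.054 to 0.15) nor Stip1 without couple 2 or 3 (0.23 and 0.067), which left 1 member past without couple 2 or 3. Neither passed without the intensity trend (0.12 and 0.18) nor Stip1 without the filter (0.075), and 5 members passed with median centring.

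Astrocyte genes were among those that rose, as were genes that mark neural stem and progenitor cells. Of 22 astrocyte genes 13 rose, 1 fell and 8 did not pass, and the counts were also 13 and 1 adjusted over the list alone (camera adjusted p = 2.3e-08, adjusted p = 0.37 with an estimated correlation). The calcium-binding protein gene S100b rose from 176 ± 40.1 to 676 ± 69.1 (log2 fold change 1.80 ± 0.15, SE; limma adjusted p = 2.8e-05). The secreted matrix protein gene Sparc rose by 2.42, the gap junction gene Gja1 and the sodium pump subunit Atp1b2 both by 0.96, and the granin Scg3 fell (−0.53). Of 32 progenitor genes 13 rose, 1 fell and 18 did not pass, and 18 rose and 3 fell adjusted over the list alone (camera adjusted p = 4.5e-04, adjusted p = 0.37 with an estimated correlation). Id1, Id3 and Id4, whose proteins block basic helix-loop-helix transcription factors, rose by 0.99, 1.92 and 1.00. Id3 went from 600.2 ± 180.0 to 2488 ± 1086 (adjusted p = 2.8e-05). The Notch modifier Lfng rose by 1.02 and the Notch ligand Dll1 fell (−0.47). In the fit without the couple as a block 7 astrocyte and 2 progenitor genes passed, and Atp1b2, Gja1, Scg3, Id4, Lfng and Dll1 did not (adjusted p = 0.42, 0.052, 0.15, 0.079, 0.13 and 0.34). Without couple 2, 8 progenitor genes passed, and Dll1 did not pass without couple 1 (0.14). Without the trend of variance on intensity 8 passed too, and Dll1 did not (0.079), and with median centring 9 rose and 3 fell.

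Neuronal and oligodendrocyte genes moved both ways. Of 30 neuronal genes 4 rose, 5 fell and 21 did not pass, and 4 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.47; median −0.06, mean 0.08, test pointing down). The neuropeptide gene Npy rose from 136 ± 19.4 to 797 ± 387 (log2 fold change 2.23 ± 0.20, SE; limma adjusted p = 3.4e-05), the granin Scg2 by 2.07, the heavy neurofilament Nefh by 1.39 and the transcription factor Bcl11b by 0.71. Those that fell were Stmn3 (−0.50), the RNA-binding protein gene Elavl2 (−0.54), the intermediate filament genes Ina (−0.55) and Nefm (−0.80), and the neuronal tubulin Tubb3 (−0.52). Of 12 oligodendrocyte lineage genes 3 rose, 3 fell and 6 did not pass, and 3 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.30). Besides Pdgfra and C1ql1 the myelin enzyme Cnp fell (−0.30), while Tmem100 rose from 63.4 ± 10.8 to 369 ± 134 (2.05, adjusted p = 1.6e-04), and the myelin genes Cldn11 and Galc rose by 1.00 and 0.50. Npy and Tmem100, 1 in each list, passed without the couple as a block, and the other genes named here did not (adjusted p from 0.064 to 0.42). Calls that ended with a couple left out were those of Cldn11 and Galc without couple 1 (adjusted p = 0.070 and 0.076) or 2 (0.15 and 0.13), Cnp without couple 1 or 3 (0.24 and 0.077), Nefm and Bcl11b without couple 1 (0.17 and 0.23) or 2 (0.073 and 0.19), Ina without couple 3 (0.089) and Tubb3 without couple 2 or 3 (0.14 and 0.18), and 3 oligodendrocyte genes passed without couple 1. Without the intensity trend 4 neuronal genes passed, and without the filter 5 neuronal and 3 oligodendrocyte genes, as under a stricter filter, where fewer were tested. Bcl11b, Cldn11, Cnp, Ina, Nefm and Tubb3 did not pass without the trend (0.056 to 0.17) or without the filter (0.051 to 0.13), Stmn3 without the trend (0.060), Galc without the filter (0.0503) and Bcl11b with quantile normalization (0.057). With median centring 8 neuronal and 5 oligodendrocyte genes fell.

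Many extracellular matrix genes rose, as did many markers of meningeal, pericyte and fibroblast cells. Of 28 genes for matrix, integrins and proteases 17 rose, 3 fell and 8 did not pass, and 20 rose and 3 fell adjusted over the list alone (camera adjusted p = 2.3e-08, adjusted p = 0.37 with an estimated correlation). The basement membrane collagen Col4a1 rose from 1201 ± 307 to 2479 ± 256 (log2 fold change 1.05 ± 0.09, SE; limma adjusted p = 2.8e-05). The protease inhibitor Timp1 rose by 1.33 and the membrane-bound metalloproteinase Mmp14 by 1.10. The chondroitin sulphate proteoglycans Vcan and Bcan (−0.82 and −0.37) and the metalloproteinase Mmp15 (−0.47) fell. Of 13 meningeal, pericyte and fibroblast markers 9 rose and 4 did not pass, and 10 rose adjusted over the list alone (camera adjusted p = 1.1e-07, adjusted p = 0.37 with an estimated correlation). Fbln2, a basement membrane glycoprotein, rose from 285 ± 154 to 875 ± 323 (1.58, adjusted p = 1.3e-05), Col6a1 by 1.64 and Igfbp2 by 0.48. Without the couple as a block 6 matrix genes and 4 markers passed, and Vcan, Bcan, Mmp15, Fbln2 and Col6a1 did not (adjusted p = 0.23, 0.55, 0.13, 0.057 and 0.089). Bcan did not pass without couple 1 (0.16). Dropping the intensity trend left 11 matrix genes past, and Vcan, Bcan and Mmp15 did not (0.076, 0.13 and 0.053), nor did Bcan without the filter (0.062).

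Few genes of DNA replication and mitosis passed with the deposited scaling. Of 30 genes of DNA replication and S phase 2 fell and 28 did not pass, with 0 past when adjusted over the list alone in limma and 13 lower and 1 higher at an unadjusted p under 0.05. The pre-initiation factor Cdc45 and the clamp loader subunit Rfc4 fell by 0.24 and 0.26 on the log2 scale. Mcm7, of the replicative helicase, had signals of 8376 ± 287 and 7110 ± 1310 (−0.25, limma adjusted p = 0.056). The list as a whole lay lower (median −0.14, camera adjusted p = 0.0014, adjusted p = 0.54 with an estimated correlation) and did not pass with fry (0.33). Of 33 genes of G2/M and mitosis the phosphatase gene Cdc25b rose (0.48) and 32 did not pass, with 0 past adjusted over the list alone in limma and 4 higher at an unadjusted p under 0.05 (camera adjusted p = 0.37). Of 24 G1 cyclins and cyclin-dependent kinase inhibitors 7 rose, 1 fell and 16 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.23). The growth arrest gene Gadd45a rose from 682 ± 113 to 1279 ± 251 (0.87 ± 0.09, SE; adjusted p = 8.8e-05), and the inhibitor genes Cdkn2b and Cdkn1a rose by 1.68 and 0.55. Myc fell from 2293 ± 362 to 1292 ± 306 (−0.83, adjusted p = 1.6e-04). In limma without the couple as a block 0 genes of the replication and mitosis lists passed (2 and 1 at an unadjusted p under 0.05), 1 gene of the G1 list did, and Myc, Cdkn1a and Cdkn2b did not (adjusted p = 0.061, 0.22 and 0.097). The replication list held 0 genes past in limma with quantile normalization (2 higher and 11 lower at an unadjusted p under 0.05), without the filter (1 and 12) and without the intensity trend (1 and 1), with adjusted p from 0.068 to 0.17 for Cdc45 and from 0.077 to 0.22 for Rfc4, and 15 lower after centring each array on its median, where 6 genes of the G1 list were higher and 6 lower. Without the filter or the trend Cdc25b did not pass (0.073 and 0.12), and without the trend 5 genes of the G1 list did. With median centring the mitosis list held 1 gene higher and 6 lower at an unadjusted p under 0.05 in limma. Without couple 2 the replication list did not pass (camera adjusted p = 0.21). In limma it then held 0 genes lower and 2 higher at an unadjusted p under 0.05, with a median of −0.08. The mitosis list did pass without couple 2 (camera adjusted p = 0.012, adjusted p = 0.61 with an estimated correlation). There Cdc45, Rfc4 and Cdc25b did not (0.26, 0.37 and 0.22), nor did these 3 without couple 1 (0.093, 0.10 and 0.079) or Cdc45 without couple 3 (0.068), where 4 replication genes passed.

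Of the genes of cholesterol synthesis that changed, most fell. Of 22 such genes 2 rose, 11 fell and 9 did not pass, and 2 rose and 14 fell adjusted over the list alone (camera adjusted p = 2.8e-05, adjusted p = 0.37 with an estimated correlation). Hsd17b7, a sterol synthesis enzyme, fell from 3487 ± 330 to 2382 ± 326 (log2 fold change −0.55 ± 0.07, SE; limma adjusted p = 2.8e-04), and Idi1 and Msmo1 fell by 0.44 and 0.35 on the log2 scale. The genes that rose were Srebf1, a transcription factor of lipid synthesis (0.82), and Insig2, which holds back sterol regulatory element binding proteins (0.43). Of 25 genes of the unfolded protein and amino acid stress response 2 rose, 7 fell and 16 did not pass, and 2 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.37 with an estimated correlation). The transcription factor Atf4 (−0.52), asparagine synthetase Asns (2074 ± 233 and 1289 ± 178, −0.68, adjusted p = 1.3e-04) and the glutathione-degrading enzyme Chac1 (−0.80) fell, and Cebpg (0.47) and the serine synthesis gene Phgdh (0.23) rose. Of 21 genes of glucose metabolism 8 rose, 1 fell and 12 did not pass, and 10 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.37 with an estimated correlation). Pdk2, a kinase that inhibits pyruvate dehydrogenase, rose by 0.71, the glycogen phosphorylase Pygb by 0.60 and Tpi1 by 0.42, and Pfkp fell (−0.25). In limma without the couple as a block Srebf1, Asns and Chac1 passed, the other genes named here did not (adjusted p from 0.057 to 0.52) and the members past were 1 cholesterol gene, 2 stress genes and 0 glucose genes (5 at an unadjusted p under 0.05), and the stress list did not pass under a stricter filter on low signals (0.061). Without the intensity trend 3 cholesterol genes (2 lower), 4 stress genes and 2 glucose genes passed, and Msmo1, Tpi1, Cebpg, Insig2, Pfkp and Phgdh did not (0.051 to 0.19). Insig2, Pfkp and Phgdh also did not pass without the filter (0.080 to 0.094), Insig2 and Pfkp with quantile normalization (0.061 and 0.075) and Insig2 and Phgdh with median centring (0.084 and 0.19), where 4 glucose genes rose and 2 fell. Without couple 2 the members past were 6, 5 and 4, without couple 1 they were 4 glucose genes, and Insig2, Pfkp and Phgdh each lost the call without any 1 couple (0.050 to 0.29).

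**Figure D2:**
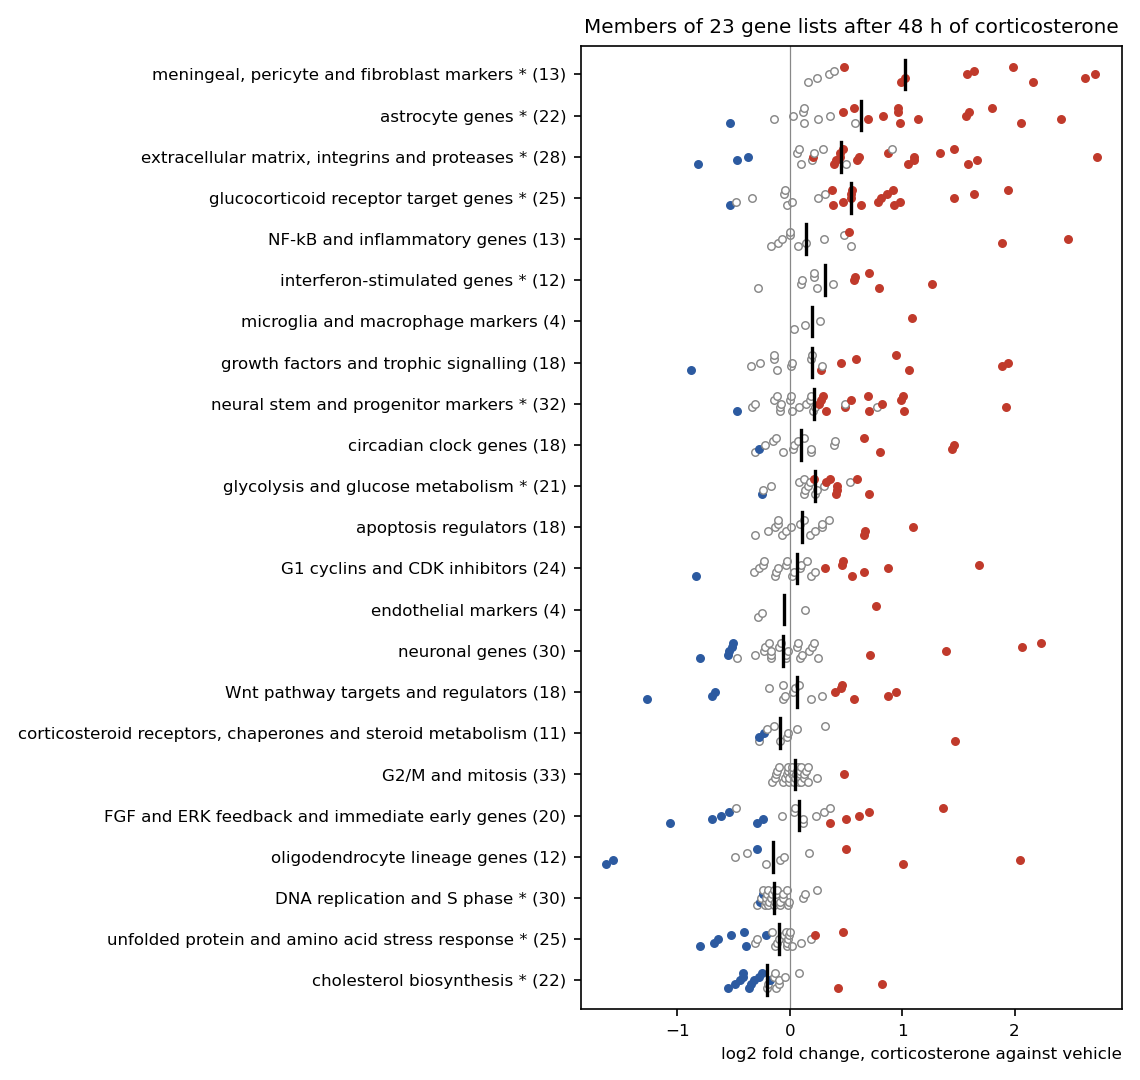
Log2 fold change (corticosterone against vehicle) of each tested member of the 23 gene lists, with members past adjusted p 0.05 filled (red higher, blue lower), the others open, the median as a bar, an asterisk at lists past the threshold with camera and the number of members tested in parentheses. The median of the tested members was 1.03 for the meningeal, pericyte and fibroblast markers and −0.20 for cholesterol biosynthesis.

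Among inflammatory and immune genes, 3 of 13 genes of the NF-kB and inflammatory list rose and 10 did not pass, and 4 rose adjusted over the list alone (camera adjusted p = 0.086). That list passed with camera without couple 1 (0.043, adjusted p = 0.64 with an estimated correlation), with median centring (0.027, and 0.28) and with the mean of a gene's probe sets (0.038, and 0.49). The genes that rose were the chemokines Ccl2, from 32.2 ± 48.8 to 268 ± 114 (log2 fold change 2.48 ± 0.30, SE; limma adjusted p = 2.6e-04), and Ccl20 (1.89), and the inhibitor Tnfaip3 (0.53). Of 12 interferon-stimulated genes 5 rose and 7 did not pass, with 5 also adjusted over the list alone (camera adjusted p = 0.0072, adjusted p = 0.37 with an estimated correlation). These were Ifi35 (1.26), the immunoproteasome subunit Psmb9 (0.79), the RNA sensor Rig1 (0.71), Ifi27 (0.58) and Mx2 (0.57). Of 4 tested microglia and macrophage markers Cd14, a lipopolysaccharide co-receptor, rose from 92.0 ± 12.2 to 236 ± 89.5 (1.09, adjusted p = 0.0043), the others did not pass, and 1 rose adjusted over the list alone (camera adjusted p = 0.30). Aif1 had signals of 59.8 ± 8.74 and 69.0 ± 16.6 (0.13, adjusted p = 0.74). Of 4 endothelial markers the transporter Slco1a4 rose (0.77), also adjusted over the list alone, and 3 did not pass (camera adjusted p = 0.91; median −0.05, mean 0.09, test pointing up, and median 0.15 over all 16 named members). Ccl2 was the member of these lists that passed without the couple as a block (the other genes named that rose had adjusted p from 0.055 to 0.40). Without couple 2 Cd14 (0.071), Psmb9 (0.11) and Slco1a4 (0.071) did not pass, Slco1a4 did not without couple 1 or 3 either (0.083 and 0.088), Tnfaip3, Rig1 and Mx2 did not without couple 1 (0.20, 0.058 and 0.096) or 2 (0.12, 0.14 and 0.088), and Mx2 did not without couple 3 (0.14), while 5 NF-kB genes passed without couple 3, and 3 and 2 interferon genes without couples 1 and 2. Without the intensity trend 2 interferon genes passed, and Tnfaip3, Psmb9, Rig1 and Mx2 did not (0.052 to 0.074). Tnfaip3, Rig1, Mx2 and Slco1a4 did not pass without the filter (0.057 to 0.11), Tnfaip3, Mx2 and Slco1a4 with quantile normalization (0.053 to 0.072), and Tnfaip3 and Mx2 with median centring (0.058 and 0.064).

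Growth factor and signalling lists held members in both directions. Of 18 growth factor and trophic genes 7 rose, 1 fell and 10 did not pass, and 9 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.057). This list passed with camera without couple 1 (0.016), without the couple as a block (0.044), with quantile normalization (0.038), median centring (0.026), a stricter filter (0.020) and a larger pseudocount (0.032), with an adjusted p = 0.28 to 0.66 with an estimated correlation in these settings. Igfbp3, an insulin-like growth factor binding protein, rose from 1532 ± 345 to 5864 ± 1851 (log2 fold change 1.89 ± 0.14, SE; limma adjusted p = 1.9e-05), the activin antagonist Fst by 1.94 and Igfbp5 by 1.06, and Tgfa fell (−0.88). Of 20 genes of FGF and ERK feedback, immediate early genes included, 5 rose, 6 fell and 9 did not pass, and 6 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.84). Those that rose were Fosl1 (1.37), Ier3 (0.71), the phosphatase gene Dusp5 (0.61) and the ETS factors Etv4 (0.50) and Etv1 (0.36), and the nuclear receptor gene Nr4a1 fell (−1.07). Of 18 Wnt genes 6 rose, 3 fell and 9 did not pass, and 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.37). The receptor Fzd1 rose by 0.87, and the Wnt antagonists Sfrp2 and Dact1 fell (−0.69 and −0.67) besides Lgr5. In limma without the couple as a block 3 growth factor, 2 Wnt and 0 FGF genes passed (4 FGF genes higher and 5 lower at an unadjusted p under 0.05), and Tgfa, Dact1, Nr4a1, Fosl1, Ier3, Dusp5, Etv4 and Etv1 did not pass (adjusted p from 0.060 to 0.56). Without couple 2 these counts were 5, 5 and 7, and Ier3 and Dusp5 did not pass (0.058 and 0.15), nor did Dusp5 without couple 1 (0.092). There were 4 FGF genes past without the intensity trend, where Dusp5 and Etv1 did not pass (0.056 and 0.084), and without the filter 5 growth factor genes passed and Dusp5 did not (0.070). With median centring 6 growth factor genes rose and 4 fell.

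Of 18 circadian clock genes 4 rose, 1 fell and 13 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.23). Besides Per1 these were the repressor Bhlhe41, from 89.7 ± 30.8 to 294 ± 88.5 (log2 fold change 1.45 ± 0.14, SE; limma adjusted p = 8.5e-05), Rorb (0.80) and Bmal1 (0.66), and the kinase gene Csnk1e fell (−0.27). Of 18 apoptosis regulators the death receptor Fas (1.10), Casp6 (0.67) and Bik (0.66) rose and 15 did not pass, with 3 past adjusted over the list alone (camera adjusted p = 0.36). Among 10 reference genes Gusb rose (0.37), the transferrin receptor Tfrc fell (−0.49) and 8 did not pass, also adjusted over the list alone. Of 3 sex-linked genes 0 passed in limma, also adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05, counted at the brightest probe set of each gene. That 1 was Xist (−0.26, adjusted p = 0.13), which fell in 2 of its 3 other probe sets (−0.45 and −0.43, adjusted p = 0.017 and 0.030). Xist passed without couple 3 (0.011), with median centring (0.049) and with the mean of its probe sets (0.030), and its adjusted p was 0.76 without the couple as a block. Per1, Bhlhe41 and Tfrc passed without the couple as a block and the other genes named here that changed did not (adjusted p from 0.069 to 0.34). Calls lost with a couple left out were those of Bmal1 and Fas without couple 2 (0.056 and 0.074), Rorb and Gusb without couple 1 (0.080 and 0.062), Bik without couple 1 or 2 (0.34 and 0.13) and Csnk1e without couple 1, 2 or 3 (0.17, 0.16 and 0.085), which left 3 clock genes without couple 1 or 2, 1 apoptosis gene without couple 2 and 1 reference gene without couple 1. In limma without the intensity trend 3 clock genes and 0 reference genes passed (1 higher and 1 lower at an unadjusted p under 0.05), and Rorb, Csnk1e, Bik, Gusb and Tfrc did not (0.057 to 0.13). Rorb, Csnk1e and Bik did not pass without the filter (0.062 to 0.15) nor Bik with quantile normalization or median centring (0.076 and 0.062), and with that centring 1 reference gene rose and 3 fell, 2 clock genes fell, and 2 apoptosis genes rose and 1 fell.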

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

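The comparison of splits and the test of scaling on the number of changed probe sets were written down before their results were seen, and the test of scaling on the share of higher probe sets was chosen after.

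Among the 12417 probe sets left out for a low signal, 109 had higher signals on all 3 corticosterone arrays than on any vehicle array and passed in limma when the filter was dropped. Separation of 3 against 3 arrays in a given direction comes up by chance in 5% of probe sets, and in either direction in 10%. The 109 also had to pass the threshold, so their number cannot be set against these shares. A total of 123 of the probe sets left out passed without the filter, 113 higher and 10 lower. The lower quartile of all signals was also higher with corticosterone in couples 1, 2 and 3 (32.0 against 23.2, 33.3 against 27.8 and 28.3 against 27.4). Of the 109, 78 carry 1 gene symbol. They include the actin-binding genes Tagln, from 4.77 to 155 (at least 5.45-fold), and Inf2, from 8.26 to 157 (at least 6.53-fold), the nuclear lamin Lmna, from 11.1 to 141, the potassium channel Kcna1, from 4.41 to 147, and the clock-related transcription factor Npas2, from 8.69 to 127. These 5 genes were chosen after their values were seen.

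Control probe sets were left out of the tests, and 4 of the 12 for rat transcripts had higher signals on every corticosterone array than on any vehicle array. The mean was 16403 ± 327 (SD, n = 3) against 14876 ± 718 with vehicle for the 5′ probe set of Gapdh and 13791 ± 587 against 12302 ± 556 for its middle probe set. It was 333 ± 33.0 against 271 ± 18.8 for the 3′ probe set of hexokinase and 182 ± 60.3 against 95.2 ± 31.9 for its middle probe set.

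The number of changed probe sets and their direction were weighed against grouping and scaling. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave 2953 probe sets, and the highest of the others gave 0 in limma with the couple as a block, including the 3 others that part all 3 couples, and 0 without it, where the real split gave 417. Quantile normalization left 88.4% of the changed probe sets past the threshold with the same sign, and median centring left 82.9%. The first value met the bound written down beforehand as counting against the authors' scaling as the cause of the calls. Median centring moved the median of the probe sets tested by over 0.1, which met the bound written down as counting for it. With both bounds met, the test does not decide. The share of changed probe sets that were higher went from 59.3% to 30.4% with that centring and to 56.4% with quantile normalization. Which direction prevailed may therefore come from the scaling, though 1 of these 2 alternatives left it as it was. An effect of corticosterone on total RNA per cell was not tested.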

How the results depend on the processing

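All alternatives were planned. Each of the 2953 changed probe sets that was tested kept its direction with other pseudocounts, with quantile normalization, with median centring and without any 1 couple. The other fits to probe sets leave fold changes as they were. These probe sets were called on the same couples, so a kept direction is no separate support for the calls. The number past was 2918 with no pseudocount, 2972 with a larger one, 2860 with quantile normalization and 2405 of 12417 tested with a stricter filter, and it moved by over 1.5 times under some of the others. Without the couple as a block 417 probe sets passed (362 higher, 55 lower; genes 297, 261 and 36), and without the intensity trend 1262 (960 and 302; genes 799, 623 and 176). Without the filter 1862 passed (624 lower; genes 1239, 410 lower), where more probe sets were tested. Median centring gave 2846 lower probe sets and 1811 lower genes, and a threshold of 0.10 gave 1905 and 1211. Leaving out a couple, which leaves fewer samples, gave 1192 to 2807 probe sets (800 to 1704 higher, 392 to 1103 lower) and 812 to 1830 genes (545 to 1151 higher, 267 to 679 lower). With an estimated correlation 0 lists passed, with 1 at an unadjusted p under 0.05, against 14 with fry and 10 to 12 without 1 couple. The fit with an estimated correlation has few residual degrees of freedom, so its count does not show how much correlation between genes matters. Other causes were not tested. Of the 126 genes named by the rule, some of which had not passed to begin with, 57 lost their call without the couple as a block and 20 without the intensity trend. Of 40 other tested genes, named after their values were seen, 34 lost their call without the couple as a block and 24 without the trend. Without the couple as a block camera changed 1 list's call (growth factors, past at 0.044). With quantile normalization 118 of 125 named genes kept both their sign and their side of the threshold. Median centring moves all probe sets of an array by 1 amount, and the median of a list relative to all genes was that of the deposited scaling. The sign turned for 5 genes, none past the threshold in the deposited scaling: Aif1 (−0.029 to 0.35 without 1 couple), Cd68 (−0.093 with quantile normalization, −0.072 with median centring, −0.029 to 0.15), Egfl7 (−0.74 to 0.063), Uty (−0.16 to 0.14) and Tsc22d3 (−0.14 to 0.083), and the cause was not tested. A stricter filter changed no call of the named genes it left in. Signal over background limits what can be seen in the 40% of probe sets left out.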

Other observations

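The tests of BMP, actin and ribosome genes were written down after the patterns that prompted them and before their genes were looked at. Those of fibroblast and microglial genes use members of the fixed lists and were chosen after the results of these lists were known, and the test over symbol families after the values of the fixed lists were seen. Among 299 families of gene symbols (598 tests, Fisher's exact test, Benjamini-Hochberg), 5 held a larger share of genes changed in 1 direction than all genes tested did. That test treats genes as independent, and no test that allows for correlation between genes was run on the families. Families were symbols alike up to their first digit, and S100 was set as a family by name. Of 18 collagen genes 10 rose (adjusted p = 0.0049, median log2 fold change 0.71), among them Col18a1 (1.59), and Col27a1 fell (−1.0). Of 8 annexins 6 rose (adjusted p = 0.017, median 1.43), with Anxa1 at 113 ± 104 and 685 ± 437 (2.32), and of 9 S100 genes 6 rose (adjusted p = 0.031, median 1.46), with S100a6 at 1.98. Of 10 semaphorin genes 6 rose (adjusted p = 0.042), and Sema3a and Sema3c, secreted axon guidance proteins like Sema3e, rose by 1.28 and 1.26. Of 29 genes of RNA polymerase subunits 9 fell (adjusted p = 0.036, median −0.20), among them Polr1b and Polr1e of polymerase I (−0.39 and −0.41). The number that fell was 2 without couple 1, 2 without couple 2, 2 without the intensity trend and 16 with median centring (median −0.31). In limma without the couple as a block 3 collagens, 4 annexins, 4 S100 genes and 1 semaphorin rose and 0 polymerase subunit genes fell (7 at an unadjusted p under 0.05), and Anxa1, Col18a1, Col27a1, S100a6, Sema3a, Sema3c, Polr1b and Polr1e did not pass (adjusted p from 0.065 to 0.30). Sema3a and Col27a1 also did not pass without couple 2 (0.057 and 0.10), nor did Polr1b and Polr1e without couple 1 or 2 (0.058 to 0.36). Without the intensity trend 3 semaphorins passed and Sema3c, Polr1b and Polr1e did not (0.066, 0.17 and 0.082), nor did Polr1b without the filter (0.12). No family turned direction with quantile normalization or median centring.

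Many ribosome biogenesis genes fell. A list of 33 such genes was drawn up because polymerase subunits and Myc were lower, and of 31 tested 26 fell and 5 did not pass. Their median log2 fold change was −0.35, below all of 10000 random lists matched on signal, which treat genes as independent. With camera the adjusted p over the 3 lists tested here was 4.4e-15 at the preset correlation. The list did not pass with camera at its estimated correlation of 0.41 (p = 0.13, adjusted p = 0.37) nor with fry (adjusted p = 0.0505). Camera with an estimated correlation rests on few residual degrees of freedom here, so it does not show how much correlation between the genes matters. Rrs1, a ribosome assembly factor, went from 2296 ± 139 to 1502 ± 75.7 (−0.60, limma adjusted p = 2.5e-04), Heatr1 from 788 ± 12.6 to 512 ± 46.6 (−0.60), and Fbl, the methyltransferase of ribosomal RNA, from 7798 ± 478 to 5953 ± 394 (−0.39). The number that fell was 24 with quantile normalization, 28 with median centring, 17, 7 and 18 without couple 1, 2 and 3, 3 without the intensity trend and 2 without the couple as a block, and Fbl did not pass in the last 2 of these settings (0.062 in both).

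Matrix and fibroblast markers were higher with corticosterone, which could come from fibroblast or meningeal cells, from a change within the progenitors, or both. Of 7 abundant genes of such cells, all of them in the fixed lists, the median log2 fold change was 0.28, against 0.60 for all named members of the marker list, 4 were bright enough to be tested and 2 passed. Postn (2.16) and Col1a2 (0.99) rose, Col1a1 (118 ± 131 and 153 ± 168) and Col3a1 (237 ± 296 and 361 ± 491) did not pass, and Dcn, Lum and Pdgfrb had treated signals of 19.8, 49.0 and 18.1. Col1a2 did not pass without couple 2 or without the filter (adjusted p = 0.12 and 0.071), and neither gene did without the couple as a block (0.70 and 0.23 for Postn) or without the intensity trend (0.075 and 0.052). Of the 4 tested, 2 rose without couple 1, 1 without couple 2 and 3 without couple 3. Their medians were 0.37, 0.66 and 0.99 there, against 0.67 with all couples. Both arrays of couple 2 held most of the Col1a1, Col1a2, Col3a1 and Lum signal: Col3a1 was at 577 with vehicle and 928 with corticosterone there, 40.8 and 94.1 in couple 1, and 93.7 and 61.9 in couple 3, where Lgals1 went from 1009 to 5492. Since part of these genes rose and the rest did not pass or lay near background, the 2 sources cannot be told apart here. Microglia as a source of the higher Cd14 and Ccl2 stay open too: of 8 abundant microglial genes, also all in the fixed lists, 7 lay below the filter, and without the filter 0 of the 8 passed in limma (1 higher at an unadjusted p under 0.05), where 123 other probe sets from below it did, and the median was 0.24. The bound written down beforehand would have counted this against microglia, but genes this close to background have folds shrunk by the pseudocount and exclude nothing. C1qb (12.3 and 33.8) and Ctss (32.8 and 59.9) had the highest log2 fold changes of the 8 (0.62 and 0.59), and Aif1 (0.13), Laptm5 (0.08) and Tyrobp (42.0 and 35.3, −0.12) the lowest.

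Id genes and Tmem100 were higher, and higher BMP-SMAD signalling was tested as a hypothesis with 12 other target genes. Of the 5 tested 1 rose (Tob1, 0.53, adjusted p = 0.051 without couple 2, 0.055 without the intensity trend and 0.32 without the couple as a block), and their median of 0.32 lay at the 88.4th percentile of 10000 random lists (camera adjusted p = 0.17), with 3 of the 5 higher at an unadjusted p under 0.05. Without couple 3, 2 of the 5 rose (median 0.25). Smad9 (0.63, adjusted p = 0.055) and Atoh8 (0.32, 0.16) were higher in all 3 couples and Smad6 (−0.40, 0.24) lower in all 3. Over the 10 with a named probe set the median was 0.08 without the filter, with Bambi, Msx1 and Grem1 also below 0, and the hypothesis stays open. Because Tagln, Tpm2 and Cav1 were higher, 20 other genes of the actin cytoskeleton and of SRF or YAP targets were examined. Of the 16 tested 6 rose (3 without the couple as a block and 3 without the intensity trend), and their median of 0.16 lay at the 99.8th percentile. The highest were the receptor Axl at 1.32 and Vcl, a focal adhesion protein, at 1.04. Amotl2 (−0.36), Tpm1 (−0.07), Srf (−0.03), Pdlim7 (−0.02) and Zyx (−0.01) lay below 0 and did not pass. The list passed with camera (adjusted p = 0.0032, adjusted p = 0.37 with an estimated correlation) and did not with fry (0.12). A wider rise of such genes is consistent with the median's place among random lists, which treat genes as independent, and is not established by it, and the median was 0.07 without couple 2.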
